A study of Mus musculus with 7 samples.

How the data were processed

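RNA was sequenced from 4 libraries of A2lox mouse embryonic stem cells, 2 uninduced and 2 treated with doxycycline at 500 ng/ml for 48 h. Groups were taken from the sample titles. Per the submitters' processing notes the tools of the study were FastQC 2.6.14, TopHat2 2.0.8, SAMtools 0.1.19, HTSeq 0.5.4p1 and DESeq for a mouse genome build named mm9, with Bowtie 0.12.9 and MACS2 2.0.10.20120913 also listed. The notes give no role or order for these tools. Results of the 2 immunoprecipitation samples and the 1 input sample were not analysed here.

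The authors' deposited table lists 21937 genes. It holds 2 columns headed MinusDOX and PlusDOX, which were read here as group means of normalized read counts. That signal is never negative and is relative to the authors' normalization. The deposited table also holds the fold change as a ratio, which the authors computed as induced over uninduced mean. That definition held for 100% of genes with a p at a relative tolerance of 1e-06. The authors' log2 fold change is on the log2 scale and is infinite where a mean is 0. The authors' p-values and adjusted p-values are given for 18283 genes, and the adjusted values equalled a Benjamini-Hochberg adjustment over those genes in 100% of cases at the same relative tolerance. Another 3654 genes were at 0 in both groups, 493 were at 0 in uninduced cells only and 621 in induced cells only. Group means sum to 17303851 and 17359374 normalized reads, which is not the depth of any library, and no interval was computed from it.

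A deposited table of normalized values per library has 4 columns whose names match no sample label, so these 4 columns were not used in any step. Groups were not assigned to them from their values, so the spread between libraries was left out by choice of method and is not shown to be unknowable. The design fixed before the data were examined was a limma model on the 4 libraries, which was not fitted for that reason. The authors' DESeq p-values took its place, with an adjusted p of 0.05 as threshold and no spread per group. A paired test, tests without single libraries, quantile normalization and a count model were not run for the same reason.

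Changes were also computed as log2 of the induced over the uninduced mean with a pseudocount of 1, which understates the change of low genes. List medians are on that scale. Gene lists were fixed from textbook markers before the data were examined, 32 in number, of which 31 had at least 3 members among the 14388 genes with a mean of 10 or more. Members of each list were counted by the authors' adjusted p and again adjusted over the list alone. Each list was tested two-sided with cameraPR of limma 3.58.1 in R 4.3.3, on signed z values made from the authors' p-values and ranked, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists. Counts and medians of a list cover its tested members only. Lists share members. Older symbols were matched through the synonyms of the GRCm38.p6 RefSeq gene table, so Map2 is listed as Mtap2, Tfap2c as Tcfap2c and Tfcp2l1 as Tcfcp2l1.

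Genes named in the text follow a rule fixed before the data were examined. It takes Neurod1, the 12 largest rises and 12 largest falls among called genes with a mean of at least 100 in the higher group, up to 4 members per list with the smallest adjusted p, and a set of single genes. Part of the rule asked that both libraries of a group lie on the same side of the other group, and that part was not applied because the library columns were not used. Genes named outside it are said to be so, and a few genes that the rule takes are not reported here.

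Gene families were formed from shared symbol stems with at least 10 tested members, and 151 families were tested for an excess of rises and of falls with one-sided Fisher's exact tests, adjusted over 302 tests. Gene order was taken from the GRCm38.p6 RefSeq table, on which 14288 tested genes were placed (99.3%). Its coordinates are of another build than mm9 and are not given. Adjacent pairs of tested genes were compared with 10000 random placements.

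The scripts were tested on simulated data. With random z values for the 14388 genes 0 of 31 lists were called, and 8 of 8 lists shifted by 1.5 SD were called. Random values do not carry the correlation between genes of the real data. That simulation therefore does not show that false list calls are controlled here. After shuffling the calls 0 family tests passed, and a planted family was recovered. The adjacency test gave a permutation p = 0.26 for scattered genes and 0.001 for planted pairs. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives tried were pseudocounts of 0.5 and 5, no minimum mean or one of 50, equal totals, a threshold of 0.01 and a 2-fold minimum. A recomputed adjustment at a minimum of 10, a correlation of 0.05 and the log2 change as the list statistic were added after seeing the data.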

Results

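The series measured the transcriptome of mouse embryonic stem cells with and without induction of NeuroD1, a basic helix-loop-helix transcription factor of developing neurons. The cells were of the A2lox line, in which a transgene under a doxycycline-responsive promoter is switched on by adding the drug to the medium. RNA was sequenced from 2 uninduced libraries and from 2 libraries of cells that had received doxycycline at 500 ng/ml for 48 h. Another 2 samples were NeuroD1 chromatin immunoprecipitations after 24 h of induction and 1 was input DNA, and none of these DNA samples was analysed here. Values below are group means of normalized read counts from the authors' deposited table, which gives no spread between libraries, and every gene-level p is from the authors' DESeq test with Benjamini-Hochberg adjustment. The depth of each library was not used here. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values may measure technical spread only. No library had doxycycline without the transgene, so effects of the drug and of NeuroD1 cannot be separated.

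The RNA comparison asked whether NeuroD1 starts a neuronal expression program in stem cells. Most tested neuronal transcription factors, Notch pathway genes and axon guidance genes rose, while most epithelial and naive pluripotency genes fell. In the authors' deposited table Neurod1 itself went from a mean of 438 to 4371 normalized reads, 9.98-fold (adjusted p = 4.5e-274). Reads of the transgene and of the endogenous Neurod1 gene were not separated. Tubb3, the neuronal beta-tubulin, rose from 845 to 10149 in the authors' deposited table (adjusted p = 5.2e-39), and Cdh1, the epithelial cadherin, fell to 0.332 times its uninduced mean (29243 to 9706, adjusted p = 3.3e-110).

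Of 18283 genes with a p-value, 6499 passed an adjusted p of 0.05, which is 35.5%. Of these, 3499 were higher after induction and 3000 were lower. A change of at least 2-fold was found for 1367 of the higher and 767 of the lower genes. The balance differed with the starting level. Among 4154 genes with an uninduced mean below 10, 370 rose and 3 fell, whereas among 4118 genes at 1000 or more, 869 rose and 1261 fell. Genes that start near 0 have little room to fall, so these counts do not compare the chance of rising and falling. The list counts below rest on genes with a mean of at least 10. Among those, apart from the 10 genes of the symbol stem Chd, 23.8% rose and 20.7% fell. Over the 14388 genes with a mean of at least 10, the median log2 change was 0.0018. The authors' normalization may itself set that median, so it does not show that total expression was unchanged.

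**Figure D1:**
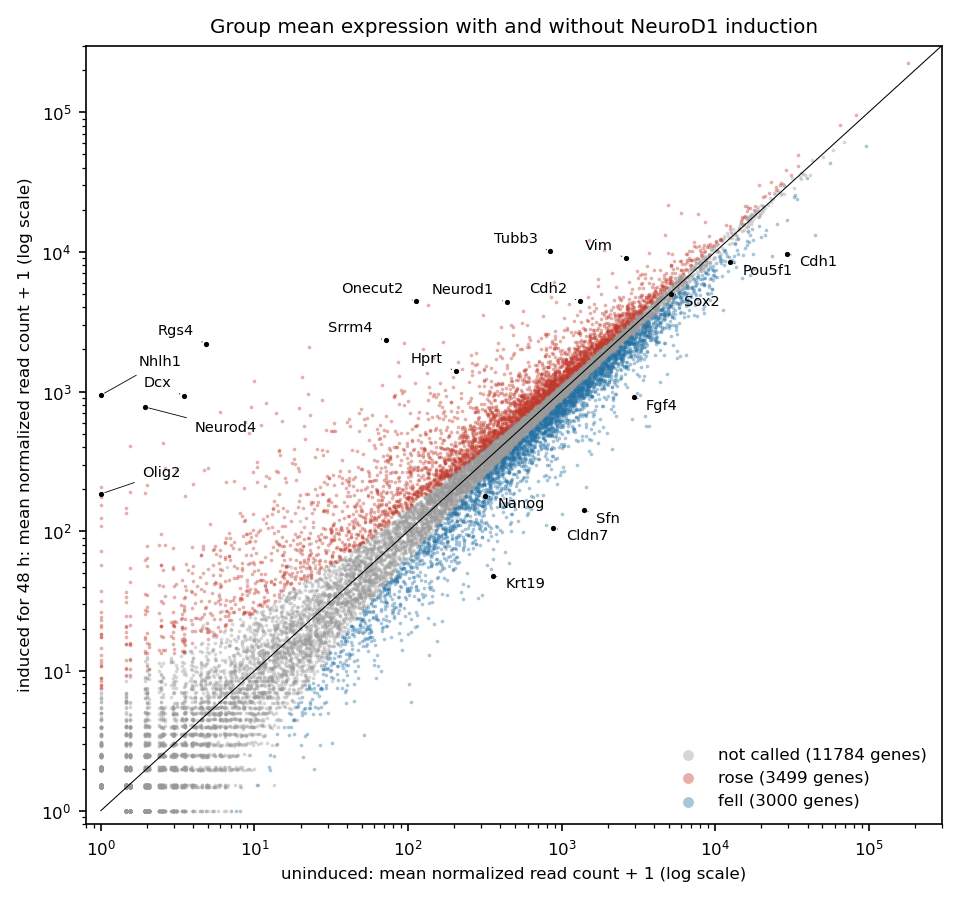
Mean normalized read count plus 1 in uninduced cells (x axis, log scale) against cells induced for 48 h (y axis, log scale), 1 point per gene with a p-value, from the authors' deposited table. Red points are the 3499 genes that rose, blue points the 3000 that fell, grey points those that did not pass, and the line marks equal means.

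Several of the largest rises started from genes listed at 0. In the authors' deposited table the uninduced mean was 0 and the induced mean 941 for Nhlh1, a helix-loop-helix factor of newborn neurons, 208 for the homeobox gene Dbx1 and 184 for Olig2, and no fold is given for them. Doublecortin (Dcx), a microtubule protein of migrating neurons, went from 2.47 to 932 in the authors' deposited table (adjusted p = 2.6e-15). In the authors' deposited table Rgs4, a regulator of G-protein signalling, rose from 3.86 to 2202 (adjusted p = 4.6e-17). Neurod4 rose from 0.928 to 776 (adjusted p = 3.1e-197) and St18 from 0.537 to 404 (adjusted p = 1.2e-17) there. The remaining genes among the 12 largest rises were Trhde, Thsd7b, Ndst4, Clvs1 and Gsbs, each with an induced mean between 123 and 425 in the authors' deposited table.

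Several of the largest falls were in genes expressed by epithelia. In the authors' deposited table stratifin (Sfn) fell from 1396 to 140 (adjusted p = 6.9e-24) and the tight junction gene Cldn7 from 882 to 105 (adjusted p = 5.7e-18). The keratin gene Krt19 was at 0.133 times its uninduced mean in the authors' deposited table. Also among the 12 largest falls were Inhbb, Serpinb6c, Ltb, Cdcp1, Napsa, Fgf17 and Slc1a1.

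Neuronal transcription factors formed the list with the highest median change. Of 31 tested members 29 rose and 0 fell, with a median log2 change of 3.64 (set test adjusted p = 9.9e-12), and adjusted over the list alone the count was also 29. Onecut2 rose from 112 to 4433 and Ebf2 from 19.3 to 1270 in the authors' deposited table. Insm1, a zinc finger factor of neuronal and endocrine precursors, rose 10.3-fold and Hes6 5.08-fold in the authors' deposited table. The proneural gene Neurog2, below the minimum mean of the list test, did not pass, with means of 0.928 and 7.46 (adjusted p = 0.12) in the authors' deposited table. Its relative Neurog1, named after its values were seen, rose from 0.464 to 19.7 in the authors' deposited table (adjusted p = 0.0041).

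Genes of the neuronal cytoskeleton and of neuronal RNA-binding proteins rose in 28 of 33 cases and fell in 1, with a median log2 change of 1.61 (set test adjusted p = 4.6e-10) and the same counts adjusted over the list alone. The splicing regulator gene Srrm4 rose 32.9-fold in the authors' deposited table. The RNA-binding protein gene Celf3 rose 18.7-fold (adjusted p = 6.2e-104) and Map2 4.57-fold (adjusted p = 2.2e-09) there. Stmn3 and Dpysl3, which act on microtubules and growth cones, rose 7.17-fold and 5.69-fold in the authors' deposited table. Ptbp1, a splicing repressor of non-neuronal cells, did not pass, with means of 8759 and 8678 (adjusted p = 1) in the authors' deposited table.

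Synapse and excitability genes rose in 22 of 35 cases and fell in 1, with a median log2 change of 1.07 (set test adjusted p = 1.5e-05). Adjusted over the list alone, 23 rose and 2 fell. Complexin 2 (Cplx2) went from 135 to 4136, the vesicle protein gene Syp rose 4.69-fold and Unc13a 3.17-fold in the authors' deposited table. The sodium channel gene Scn3a rose 4.47-fold in the authors' deposited table.

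In the list of axon guidance, adhesion and migration genes 30 of 37 rose and 3 fell, with a median log2 change of 1.93 (set test adjusted p = 4.0e-08) and the same counts adjusted over the list alone. Slit1, a repulsive guidance cue, rose 15.0-fold and the semaphorin gene Sema6d 15.5-fold in the authors' deposited table. The cell adhesion genes Nrcam and Ncam1 rose 7.04-fold and 3.38-fold in the authors' deposited table.

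Notch pathway genes rose in 17 of 24 cases and fell in 2, with a median log2 change of 1.06 (set test adjusted p = 1.5e-05), and adjusted over the list alone 18 rose and 2 fell. The ligand genes Dll3, Dll4 and Dll1 rose 7.80-fold, 61.0-fold and 3.54-fold in the authors' deposited table. The ligand gene Jag2 and the receptor gene Notch4, the members that fell, were at 0.552 and 0.385 times their uninduced means in the authors' deposited table and were named after their values were seen. Mfng, which encodes a glycosyltransferase acting on Notch, rose 4.40-fold in the authors' deposited table. Repressors of neurogenesis rose as well, in 10 of 14 cases with 1 fall, a median log2 change of 1.88 (set test adjusted p = 0.00034) and the same counts adjusted over the list alone. Hes1, Hes5, Hey1, Hey2 and Heyl, which all rose, are in this list and in the Notch list, so the 2 results are not independent. Of these, Hes1, Hey1, Hey2 and Heyl were named after their values were seen. The Notch effector gene Hes5 rose 24.0-fold in the authors' deposited table. Members outside the Notch list include Id1, Id2 and Id4, which rose 4.62-fold, 4.85-fold and 12.2-fold in the authors' deposited table. The member that fell was Rest, the repressor of neuronal genes in other cells, at 0.658 times its uninduced mean in the authors' deposited table (adjusted p = 7.6e-12).

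Neural progenitor genes rose in 16 of 20 cases and fell in 0, with a median log2 change of 1.64 (set test adjusted p = 1.5e-05), and adjusted over the list alone 16 rose and 1 fell. Fabp7, the brain lipid-binding protein gene, rose from 12.7 to 706 in the authors' deposited table. The patterning genes Irx3 and Zic1 rose 15.6-fold and 30.6-fold in the authors' deposited table. Of 33 Hox genes 13 were tested, and 8 of these rose and 0 fell, with a median log2 change of 1.26 (set test adjusted p = 0.0012) and 9 rises adjusted over the list alone. Among the Hox genes below the minimum mean Hoxa10, named after its values were seen, fell from 11.4 to 1.04 in the authors' deposited table (adjusted p = 0.017). Hoxb3, an anterior member, went from 26.4 to 383 in the authors' deposited table. Retinoic acid targets, which share Hox genes with that list, rose in 7 of 12 cases and fell in 1 (median log2 change 1.08, set test adjusted p = 0.019). The retinoic acid call was lost at a higher inter-gene correlation (adjusted p = 0.0504). Its members Stra6 and Cyp26b1 rose 5.13-fold and 5.90-fold in the authors' deposited table.

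Naive pluripotency genes fell in 20 of 23 cases and rose in 1, with a median log2 change of -1.04 (set test adjusted p = 4.0e-08) and the same counts adjusted over the list alone. Fgf4 fell to 0.310 and Tfcp2l1 to 0.357 times their uninduced means in the authors' deposited table, and Nanog went from 318 to 179 (adjusted p = 2.2e-06). The member that rose was Gbx2, also a patterning gene of the anterior hindbrain, at 7.16-fold in the authors' deposited table. General pluripotency genes fell in 9 of 14 cases and rose in 1, with a median log2 change of -0.43 (set test adjusted p = 0.0042) and the same counts adjusted over the list alone. Pou5f1, which encodes Oct4, went from 12528 to 8404 in the authors' deposited table (adjusted p = 0.00051). Sox2, a factor of stem cells and of neural progenitors alike, had means of 5178 and 5017 in the authors' deposited table and did not pass (adjusted p = 0.78). Tdgf1 and L1td1 fell to 0.421 and 0.486 times their uninduced means in the authors' deposited table.

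Epithelial genes fell in 24 of 25 cases and rose in 0, with a median log2 change of -1.56 (set test adjusted p = 9.9e-12) and the same counts adjusted over the list alone. Epcam fell to 0.277 and the protease inhibitor gene Spint2 to 0.375 times their uninduced means in the authors' deposited table. Mesenchymal genes rose in 10 of 17 cases and fell in 2, with a median log2 change of 0.97 (set test adjusted p = 0.029). The mesenchymal call was lost at a minimum mean of 50, with a median log2 change of 0.28 (adjusted p = 0.070), and at a higher inter-gene correlation (adjusted p = 0.081). The repressor genes of Cdh1, Zeb1 and Zeb2, rose 7.18-fold and 5.77-fold, vimentin (Vim) 3.45-fold and the neural cadherin Cdh2 3.38-fold in the authors' deposited table.

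**Figure D2:**
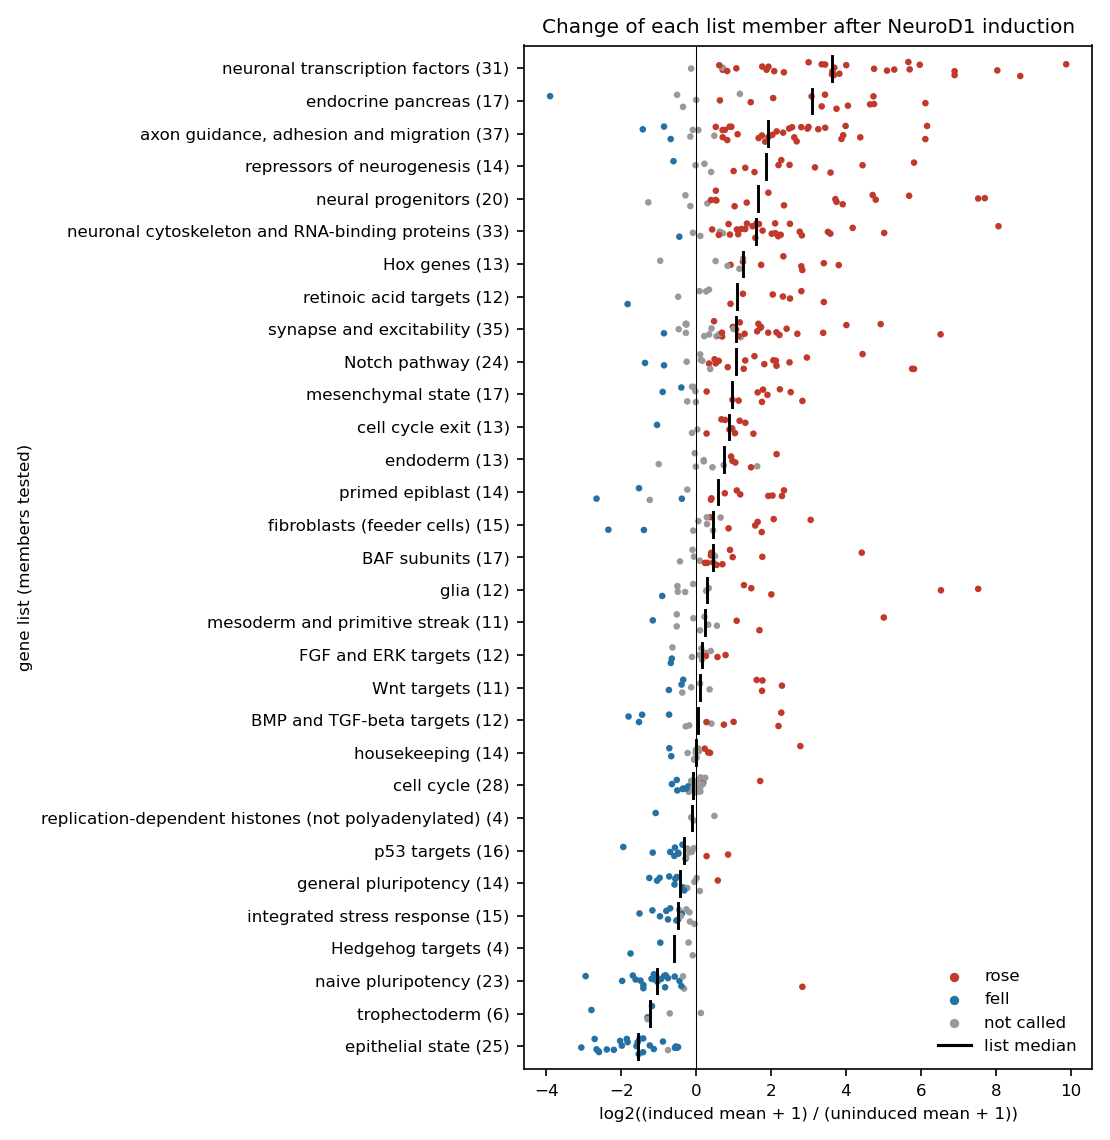
Log2 change of the induced over the uninduced mean, each plus 1 normalized read (x axis), for the tested members of the 31 gene lists (y axis, number of members in brackets). Each point is a gene, coloured by whether it rose, fell or did not pass, and black bars are list medians, from 3.64 for neuronal transcription factors to -1.56 for epithelial genes.

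Lists of other cell types were measured beside these. Fibroblast genes, which stand for the feeder cells on which the line was first grown and which the culture protocol removed, rose in 7 of 15 cases and fell in 2, with a median log2 change of 0.45 (set test adjusted p = 0.063). That list passed with no minimum mean (median log2 change 0.76, adjusted p = 0.028), at a minimum of 50 (adjusted p = 0.034) and with the log2 change as the statistic (adjusted p = 0.016). The fibroblast list did not pass at a higher inter-gene correlation (set test adjusted p = 0.14). Its muscle actin gene Acta2 rose 2.99-fold and Lox, a collagen cross-linking enzyme, 8.68-fold in the authors' deposited table. Endocrine pancreas genes rose in 12 of 17 cases and fell in 1 (median log2 change 3.08, set test adjusted p = 0.00059), out of 28 members fixed. Its hormone genes Ins1, Ins2, Gcg and Iapp were below the minimum mean and listed at 0 in both groups in the authors' deposited table, whereas the hormone gene Sst, also made by neurons, rose from 0.464 to 35.6 (adjusted p = 1.3e-09), and these genes were named after their values were seen. Its secretory granule genes Chgb and Scg3 rose 75.9-fold and 17.1-fold in the authors' deposited table, and both are also used by neurons. Glial genes rose in 5 of 12 cases and fell in 1 (median log2 change 0.30, set test adjusted p = 0.25). The glutamate transporter gene Slc1a2 went from 21.5 to 2089 and Slc1a3 fell to 0.534 times its uninduced mean in the authors' deposited table.

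Markers of the germ layers and of early embryonic tissues were tested as well. Mesoderm and primitive streak genes rose in 3 of 11 cases and fell in 1 (set test adjusted p = 0.60). Endoderm genes rose in 5 of 13 cases with 0 falls (median log2 change 0.74, set test adjusted p = 0.032), a call that was lost at a higher inter-gene correlation (adjusted p = 0.081). The basement membrane collagen genes Col4a1 and Col4a2, members of that list expressed by many cell types, rose 2.07-fold and 2.77-fold in the authors' deposited table. Trophectoderm genes fell in 3 of 6 cases with 0 rises (median log2 change -1.24, set test adjusted p = 0.029), and this call too was lost at the higher correlation (adjusted p = 0.0504). Primed epiblast genes rose in 9 of 14 cases and fell in 3 (median log2 change 0.59, set test adjusted p = 0.094). Among them Sall2 rose 3.81-fold, and Nodal and Cldn6 fell to 0.347 and 0.158 times their uninduced means in the authors' deposited table.

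Genes of cell cycle exit rose in 9 of 13 cases and fell in 1 (median log2 change 0.89, set test adjusted p = 0.0038). Btg2, an antiproliferative gene, rose 2.89-fold and the cyclin-dependent kinase inhibitor gene Cdkn1c 2.49-fold in the authors' deposited table. Cell cycle genes fell in 8 of 28 cases and rose in 2 (median log2 change -0.094, set test adjusted p = 0.15). Mki67 was at 0.705 times its uninduced mean and cyclin D1 (Ccnd1) rose 3.28-fold in the authors' deposited table. Targets of p53 fell in 9 of 16 cases and rose in 2 (median log2 change -0.32, set test adjusted p = 0.0018), and 11 fell adjusted over the list alone. Integrated stress response genes fell in 9 of 15 cases with 0 rises (median log2 change -0.48, set test adjusted p = 0.00013). Perp, a p53 target that is also an epithelial junction gene, fell to 0.259 and the stress gene Trib3 to 0.347 times their uninduced means in the authors' deposited table.

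Chromatin remodelling genes of the BAF complex rose in 12 of 17 cases with 0 falls (median log2 change 0.45, set test adjusted p = 0.00066). Arid1b rose 1.97-fold and Smarce1 1.87-fold in the authors' deposited table. No call was made for targets of Wnt (4 of 11 rose and 3 fell, set test adjusted p = 0.58), of BMP and TGF-beta (5 of 12 rose and 4 fell, adjusted p = 0.92) or of FGF and ERK (3 of 12 rose and 2 fell, adjusted p = 0.34). Hedgehog targets had 2 falls among 4 tested genes (median log2 change -0.58, set test adjusted p = 0.063), with Gli1 at 0.297 times its uninduced mean in the authors' deposited table. Replication-dependent histone genes had 1 fall among 4 (set test adjusted p = 0.52). Housekeeping genes had 4 rises and 2 falls among 14 (median log2 change 0.0051, set test adjusted p = 0.71). Gapdh did not pass (1.05-fold, adjusted p = 0.42), Actb rose 1.17-fold (adjusted p = 0.012) and Hprt rose from 203 to 1402, 6.91-fold (adjusted p = 4.8e-120), in the authors' deposited table. A list of 15 mitochondrially encoded genes was not analysed here.

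The set test ranked genes by the authors' p-values and used a preset correlation of 0.01 between genes, because a correlation estimated from libraries was not used here. At that setting 14 lists were higher and 6 lower of 31, and with a correlation of 0.05 the number called was 16 in place of 20. Where no count adjusted over the list alone is given above, it was 13 rises for endocrine pancreas, 8 for fibroblasts, 6 for endoderm, 13 for BAF subunits and 10 falls for the integrated stress response, with the other counts the same. Median, mean and test had the same sign in each of the 31 lists.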

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

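The recomputed adjustment at a minimum mean of 10, the correlation of 0.05 and the log2 change as list statistic were chosen after the data were seen. Requiring a 2-fold change in addition to the adjusted p gave 1367 higher and 767 lower genes in place of 3499 and 3000, and the smaller number follows from the added condition. Counts of higher genes ranged from 2856 (threshold of 0.01) to 3549 (minimum of 10) under the other settings, and counts of lower genes from 2365 to 3087. Rescaling to equal totals shifted log2 changes by -0.0046 and is not able to change calls that rest on the deposited p-values. A pseudocount added to both means cannot turn a direction, so the other pseudocounts test only sizes. Of 144 named genes, the 142 and 136 that had values at minimum means of 10 and 50 stayed on the same side of the threshold. Many of them were chosen for a small adjusted p, and the same p-values were adjusted again. Few could have crossed the threshold, so this is a weak check. List calls numbered 21 with no minimum, 19 at a minimum of 50 (where the trophectoderm and histone lists had too few members to be tested), 16 at a correlation of 0.05 and 21 with the log2 change, against 20. The cause of the changed list calls was not tested. No paired analysis was possible because the columns used are group means and carry no replicate numbers, and columns per library were not assigned to groups from their values. Leaving out libraries, quantile normalization, a constant prior variance, an estimated inter-gene correlation, edgeR and DESeq2 were not run, since the columns per library were not used. So no result was checked against the loss of 1 library, and depth was not used.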

Other observations

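Genes that share a symbol stem were tested as families not fixed in advance, and 7 of 302 tests passed. A stem can take in unrelated genes and pseudogenes, such as Slc7a6os, Ppp4r1l-ps and Tmem92-ps, which are in the counts. The family tests did not match genes on starting level and treated members as independent. Of genes with an uninduced mean from 10 to below 100, 361 of 3441 fell, against 1261 of 4118 at 1000 or more. The p-values of the families may therefore overstate a family effect. Genes of the stem Slc, mostly solute carriers, fell in 110 of 266 cases, 41.4% against 20.4% of other genes (one-sided Fisher's exact test, adjusted p = 3.5e-12). Among them were the glucose transporter gene Slc2a3 and the amino acid transporter genes Slc7a3 and Slc7a5, at 0.297, 0.306 and 0.471 times their uninduced means in the authors' deposited table. Clustered protocadherin genes of the beta group rose in 19 of 19 cases (adjusted p = 2.1e-10), with Pcdhb22 up 13.2-fold in the authors' deposited table. These genes lie in 1 cluster and are closely similar in sequence, so how reads were divided among them is uncertain and they are not independent. Several, such as Pcdhb7 (0 and 23.2) and Pcdhb13 (0.928 and 26.5), reached the minimum mean of 10 only through induced cells. Such genes had almost no room to fall, and low genes that did not respond were left out. The p of this family may therefore overstate the excess of rises. The same applies to some members of other families, such as Cacna2d3 (2.54 and 22.6). Calcium channel subunit genes (Cacna) and septin genes each rose in 10 of 12 cases (adjusted p = 0.0014 for both). Cacna1e rose 6.75-fold and Sept3 2.25-fold in the authors' deposited table. Genes of the stem Ppp, mostly phosphatase subunits, rose in 26 of 58 cases (adjusted p = 0.018) and Dock genes in 8 of 11 (adjusted p = 0.036), while genes of the stem Tmem fell in 67 of 186 (adjusted p = 9.6e-05). Family members were named after their values were seen.

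Tests of housekeeping genes, of feeder cells, of cells that kept uninduced expression, of overlapping or related neighbours and of low uninduced expression were chosen after the result was seen. The test of genes beside Hprt and the first count of adjacent pairs were written beforehand, but the request that a median clear its bound by 1 SD was added after the Hprt values were known. Without that request the bound of 0.5 would have counted against spreading transcription.

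Hprt rose 6.91-fold in the authors' deposited table. In the A2lox line the inducible cassette is placed upstream of Hprt. A shift shared by housekeeping genes was argued against by the other 13 genes of the list, with a median log2 change of -0.0043 and a highest value of 0.37. Transcription spreading from the insertion site into neighbouring genes cannot be told apart from none, since the 4 nearest tested genes had a median log2 change of 0.17 with an SD of 0.77, with Phf6 at 0.73 and Mospd1 at 0.74 and Fam122b at -0.77, genes named for their position. Read-through from the cassette into Hprt alone may also account for the rise and stays open, as does regulation by NeuroD1, since read positions were not used here.

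Pluripotency genes fell to intermediate levels, with a median log2 change of -1.04 in the naive list. If 0.5 of the cells in the induced cultures had kept uninduced expression, abundant genes could not fall far below 0.5 times their mean, given equal RNA per cell. Of 1261 called lower genes with an uninduced mean of at least 1000, 12 were at 0.25 times that mean or less, among them Sfn and Cldn6, and for 11 an approximate upper limit made from the p-value was below 0.5 times. That argues against so large an unresponsive share. A smaller unresponsive share, slow decay of transcripts or partial repression stay open and were not tested.

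Genes that rose may lie next to each other more often than chance. Among 1295 placed genes that rose at least 2-fold, 204 adjacent pairs both rose, with pairs sharing a symbol stem left out, against a median of 113 in random placements (95% range 94 to 132, permutation p = 0.0001, the smallest that 10000 placements can give). Reads shared between overlapping genes or related neighbours were argued against, since without pairs that overlap or share the first letters of their symbol 184 pairs remained against a random median of 101 (permutation p = 0.0001). Low uninduced expression of neighbours was argued against too, with 204 pairs against a median of 110 when genes were placed at random only among genes of similar uninduced mean (permutation p = 0.0001). For 745 genes that fell at least 2-fold the count was 87 pairs against 37 (permutation p = 0.0001), and neither follow-up was run on them. Gene length, unannotated read-through and shared regulation of neighbours were not tested and stay open.

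A different share of feeder cells between the groups was tested on the fibroblast list, where 2 called members, Thy1 and Dcn, fell while 7 rose. The bound for this test was set at that value after it was seen and stem cells may express several of these genes, so a changed feeder share stays open. Its most abundant called members were Tagln (2745 and 3583) and Acta2 (904 and 2702) in the authors' deposited table. The collagen genes of the list were divided. Col1a1 (970 and 1329), Col1a2 (1042 and 1088) and Col5a1 (1571 and 1491) did not pass in the authors' deposited table. Col3a1 (265 and 485) and Col6a1 (77.4 and 263) rose there. Apart from Acta2 and Col6a1, the genes in this paragraph were named after their values were seen.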
